A study of Mus musculus with 59 samples.

How the data were processed

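RNA of 59 striatal samples was labelled and hybridised to MouseRef-8 V2 bead arrays, per the labels' protocols, and scanner output was exported with BeadStudio 3.4.0, per the submitters' processing notes. The deposited exports hold an intensity per probe and array on a linear scale, described per the file headers as average signal and used here as not normalized, from 24.2 to 29929.1 over all arrays. Detection values, which rise with the signal, stand beside the intensity values in the export used for 24 h, per the file headers, and 1 minus such a value was used as the detection p. In the exports 17 arrays matched no sample and were not used, and 837 lines held a name and no value. A deposited table of ratio values, made by the authors by a step the sources used here do not give, was set against the intensities: each value equals the raw intensity times 1 factor per array, divided by the Sham mean of that probe and time. Its direction is therefore sample over Sham, its column medians lay between 0.924 and 1.056, and how the factors were chosen stays unknown.

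Background was corrected by normexp with detection values (limma 3.58.1 in R 4.3.3, statmod 1.5.0, offset 16), followed by quantile normalization and log2. Detection values were each array's own at 24 h (15 arrays). Elsewhere they were borrowed by signal rank from the 24 h arrays, a limit on every call of detection at 0, 3 and 8 h. Tested at 24 h, where both exist, borrowed values gave the same call for 95.3% to 100% of probes, and 50.6% to 59.1% of probes were detected there. Of 25697 probes, 23876 were named through an accession in a RefSeq table of mouse genes (GRCm38.p6, no coordinates used), 728 by a current and 709 by an older symbol, and 384 kept the array's design name. A gene took its probe with the highest mean over all arrays. Of 17877 gene names, the 12470 detected (p under 0.05) on at least 3 arrays were tested. Other probes of a called gene pointed the other way for 27 of 234 genes with several probes in HI against Sham at 3 h, 272 of 670 at 24 h, 61 of 456 and 264 of 778 in HIPC against Sham at 3 and 24 h, and 368 of 902 in HIPC against HI at 24 h.

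Samples were grouped by treatment and time from their titles, and 1 limma model over all 16 groups gave HI, PC and HIPC against Sham and HIPC against HI at each time (lmFit, eBayes with trend, Benjamini-Hochberg adjusted p under 0.05). F tests asked whether the HI effect differed between times, whether PC and HI interacted, and, with slide as a random block, whether Sham differed between times. Lists of genes, 29 fixed before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over 464 tests. Of these 134 passed, 10 of them also with an estimated correlation and 47 of them also limma's rotation test, which asks whether a list moves 1 way on balance and was passed by 56 of the 464. The apoptosis machinery and lymphocyte lists passed in no comparison, and in no passing list did mean, median and test differ in sign. Named genes were, by a rule fixed at the same time, up to 8 of the largest rises and falls with adjusted p under 0.05 and arrays that did not overlap, up to 4 members of each list that passed or had 3 passing members, the 8 smallest p of each F test, and a panel of 19 genes, of which 16 were measured. Where all arrays of the dimmer group lacked detection, a fold is a lower bound against the detection floor of those arrays and is written as at least that fold.

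Replicate numbers come from the titles. Same-numbered arrays deviated together, with every correlation over 0.1, in HI against Sham at 0 h (0.287 to 0.671), PC against Sham at 0 h (0.173 to 0.801), HIPC against HI at 0 h (0.259 to 0.768) and HIPC against Sham at 8 h (0.232 to 0.304), and the fit with replicate number as a block is given beside a result there where it ended a call or moved a count by over 1.5 times. Of 81 pairs of arrays of a group, 3 lay closer together than any pair of different groups (SD of the log2 difference 0.139) and were kept as separate samples and averaged in an alternative. Alternatives covered background, scaling, detection filter, probe choice, slide and replicate blocks, array weights, the arrays fitted, the deposited ratios and leaving out each array. In 16 simulated comparisons the fit recovered 35.1% to 59.2% of planted log2 changes of 0.5, 85.3% to 95.1% of 1 and 96.7% to 100% of 2. It made 2 to 14 other calls, but 1506 in a wrong split of real arrays (PC and Sham, 0 h). Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.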

Results

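Gene expression was measured in the striatum of C57/Bl6 mouse pups labelled 8 days old, on 59 MouseRef-8 V2 expression arrays, with 1 sample per array. The labels name 4 treatments. Sham pups were the controls, PC pups were preconditioned with hypoxia, HI pups had the right carotid artery closed and then breathed 8% oxygen for 1 h, and HIPC pups had both the preconditioning and the HI. Each treatment was sampled at time labels 0, 3, 8 and 24 h, which gave 16 groups of 4 arrays, or of 3 arrays for HI at 0 h, HIPC at 3 h, PC and HI at 8 h and PC at 24 h. The source label calls the tissue infarct striatum in every group. When the preconditioning was given, and whether Sham pups breathed low oxygen, is not settled by the labels. Median raw signals of the arrays lay between 47.7 and 102.5, and 12470 genes entered every test. The number of arrays limits the precision. Nothing in the labels ties an array to a named animal or litter, so p-values measure only the spread between these samples. The design asks how HI alone, PC alone and both together changed expression at each time, and whether PC changed the response to HI.

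Time label separated the arrays more than treatment did. The first principal component held 60.4% of the variance. Arrays lay from 24.8 to 51.3 at 8 h and from 42.4 to 50.4 on slides 2 to 4 of 0 h, but from -0.8 to 4.6 on slide 1 of 0 h, from -40.7 to -22.3 at 3 h and from -57.2 to -34.7 at 24 h. Every slide held arrays of 1 time, so all comparisons between treatments were made within a time. At every time the position on the slide followed treatment, so position and treatment cannot be told apart. Before 24 h a slide held at most 1 array of each group, so no count was fitted within a slide. List values are mean log2 changes, and values without an array are given where leaving it out ended a call, turned the sign or moved the value of a list that passed by over 1.5 times. Brain region markers also differed between arrays of a group. Thalamic, hypothalamic and midbrain markers, 32 genes chosen after the data were seen, ranged from -1.36 to 1.35 in Sham and from -1.56 to 1.21 in HI at 3 h, relative to the Sham mean on the log2 scale. They averaged 0.95 ± 0.20 (SD, n = 4) in PC and 1.17 ± 0.18 (SD, n = 3) in HIPC at 3 h. Cortical excitatory neuron markers at 24 h averaged 0.63 ± 0.25 (SD, n = 4) in HI and -0.36 ± 0.12 (SD, n = 4) in HIPC. Striatal projection neuron genes averaged 0.61 ± 0.58 (SD, n = 4) in HIPC at 24 h. From Xist and Ddx3y, Sham at 0 h held 4 females and 0 males, HIPC at 8 h 0 females and 4 males, and HIPC at 24 h 4 females and 0 males, against 1 female and 3 males in Sham at 24 h.

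**Figure D1:**
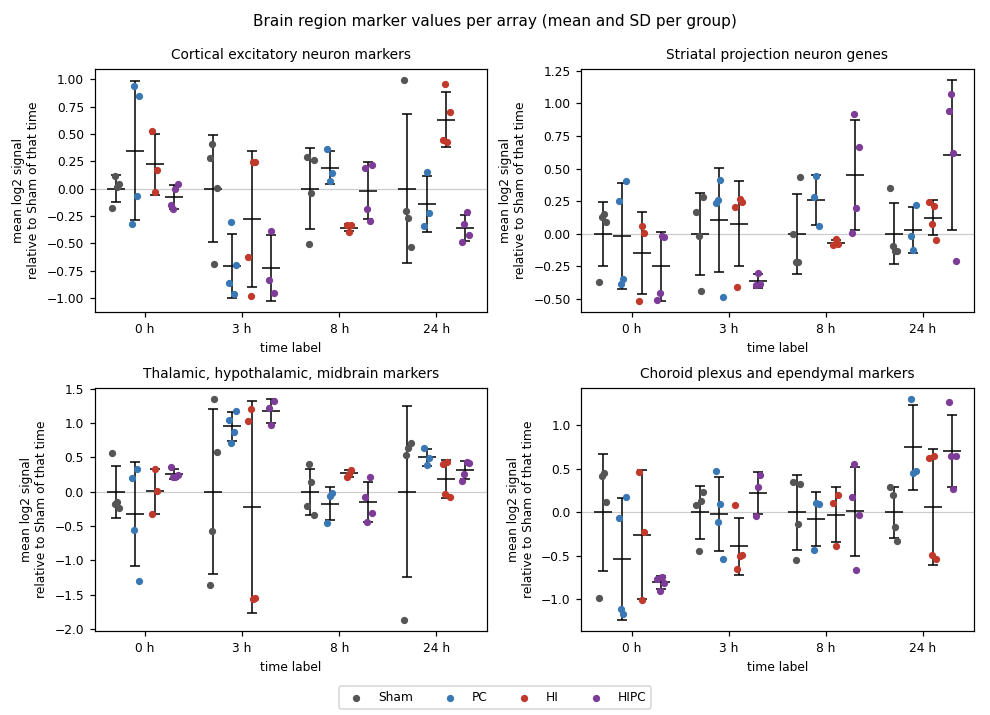
Mean log2 signal of 4 lists of brain region markers on each array, relative to the Sham mean of the same time label. Points are arrays coloured by treatment, and bars give the mean and SD of 3 or 4 arrays, such as 0.63 ± 0.25 for cortical markers in HI and -0.36 ± 0.12 in HIPC at 24 h.

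At 0 h in HI, 13 genes rose over Sham and 0 fell (limma, n = 3 HI and 4 Sham). Depp1, a FoxO-responsive gene, rose by 2.94 ± 0.35 on the log2 scale (± standard error throughout, limma, adjusted p = 8.78e-07). Ier3, an immediate early gene, rose by 1.43 ± 0.26 and Edn1, which encodes the vasoconstrictor endothelin 1, by 1.49 ± 0.30. The ceramidase gene Acer2 rose by 1.39 ± 0.26 and S100a8, a calcium-binding protein of neutrophils, by 2.71 ± 0.56, beside the stefin A family genes Stfa1 (2.50 ± 0.55) and Cstdc4 (2.04 ± 0.35) (limma, adjusted p from 0.00221 to 0.0377). Slc2a1, the glucose transporter GLUT1, rose by 0.80 ± 0.18 and passed (adjusted p = 0.0377), 1 of 16 measured genes of a panel fixed in advance, while the other 15 lay from -1.02 to 2.30, with Fos at 2.30 ± 0.54 (adjusted p = 0.0699). Among the 27 measured glucocorticoid-responsive genes, 0 passed singly and 8 adjusted over the list alone. These genes averaged 0.43 (0.43 with slide as a block, 0.34 to 0.50 within slides, camera adjusted p = 3.30e-15, adjusted p = 0.00785 with an estimated correlation). Of 10 measured neutrophil and monocyte markers 1 rose and 0 fell, with 6 passing adjusted over the list alone. Their mean change was 0.66 (0.61 with slide as a block, 0.18 to 1.15 within slides, camera adjusted p = 3.92e-10, 0.00785 with an estimated correlation). Red blood cell genes lay at 0.227 to 0.489 on HI and -0.114 to 0.139 on Sham arrays. Of the 33 measured cytokine, chemokine and NF-kB target genes, 2 rose, 0 fell and 31 did not pass, with 4 passing adjusted over the list alone. On average they changed by 0.32 (0.32 with slide as a block, 0.29 to 0.33 within slides, camera adjusted p = 4.10e-05, adjusted p = 0.409 with an estimated correlation). An unadjusted p under 0.05 was found for 556 genes. The count was 16 with slide as a block, 4 without slide 1, 3 with only these arrays fitted and 47 with array weights. It was 6 with close arrays averaged, 8 with sex and 22 with region markers as covariates. It was 8 without Sham 1 or 3, 5 without HI 1 and 3 without HI 3. Stfa1 did not pass with region markers as covariates, at 2.42 ± 0.57 (adjusted p = 0.0563). Calls were lost (highest adjusted p) for Ier3 without HI 2/3 (0.0807), Edn1 without Sham 1/4 or HI 2/3 (0.197), Acer2 without HI 1/3 (0.08), S100a8 and Stfa1 without Sham 1/2/3 or HI 1/3 (0.28 and 0.462), Cstdc4 without HI 1 (0.085), Slc2a1 without Sham 1/2/3/4 or HI 1/2/3 (0.348).

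At 3 h after HI, Fos, Ccl4 and Mobp were among the genes that rose over Sham, and Akr1c19 and Dcx among those that fell (n = 4 and 4). Fos rose by 3.86 ± 0.50 on the log2 scale and Fosb, another AP-1 gene, was at least 7.98-fold higher, since Sham arrays did not detect it (limma, adjusted p = 2.17e-06 and 1.96e-07). The chemokine genes Ccl4 and Ccl3 rose by 4.23 ± 0.73 and 2.64 ± 0.58, the cytokine-signalling suppressor Socs3 by 2.43 ± 0.36 and the TWEAK receptor Tnfrsf12a by 2.16 ± 0.34 (limma, adjusted p from 1.47e-05 to 0.00311). Lcn2, the iron-siderophore carrier lipocalin 2, was at least 5.96-fold higher (adjusted p = 0.00393), and S100a8 rose by 2.18 ± 0.51 (adjusted p = 0.00522). Red blood cell genes lay at 0.267 to 0.443 on HI and -0.147 to 0.106 on Sham arrays. Akr1c19, an aldo-keto reductase, fell by 1.28 ± 0.21, Dcx, the doublecortin of migrating neuroblasts, by 1.20 ± 0.26, the polysialyltransferase St8sia2 by 1.08 ± 0.15, and Aif1l and the protocadherin Pcdhb19 by 0.91 ± 0.13 and 0.89 ± 0.17 (limma, adjusted p from 5.94e-06 to 0.00309). Of the 16 panel genes 7 passed, Fos, Ccl3, Ccl4 and Slc2a1 among them, and the other 9 lay from -1.53 to 0.77.

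Among the 35 measured immediate early genes, 17 rose, 0 fell and 18 did not pass, with 25 passing adjusted over the list alone. The stress transcription factor gene Atf3 was at least 4.13-fold higher and Gadd45b rose by 2.14 ± 0.32. The mean of the list was 1.07 (1.07 with slide as a block, 0.067 to 2.16 within slides, camera adjusted p = 1.39e-21, adjusted p = 0.102 with an estimated correlation). It lay at 0.15, 0.21, 1.95 and 1.97 on HI 1 to 4. Of 33 measured cytokine, chemokine and NF-kB target genes, 17 rose, 0 fell and 16 did not pass, with 19 passing adjusted over the list alone. Together these genes averaged 0.94 (0.94 with slide as a block, 0.35 to 1.47 within slides, camera adjusted p = 1.50e-19, adjusted p = 0.0355 with an estimated correlation). The list lay at 0.30, 0.51, 1.45 and 1.48 on HI 1 to 4, and HI 3 and HI 4 were a pair closer than any arrays of different groups. Of the 27 measured glucocorticoid-responsive genes, 14 rose, 0 fell and 13 did not pass, with 18 passing adjusted over the list alone. Gjb6, the connexin 30 gene, rose by 1.05 ± 0.23. The listed genes averaged 0.64 (0.64 with slide as a block, 0.54 to 0.69 within slides, camera adjusted p = 1.92e-16, adjusted p = 0.00761 with an estimated correlation). Among the 40 measured hypoxia and HIF targets, 7 rose, 0 fell and 33 did not pass, with 7 passing adjusted over the list alone. Slc2a1 rose by 1.17 ± 0.16 and Ddit4, an inhibitor of mTOR, by 0.55 ± 0.12, and the vasodilator peptide gene Adm was at least 1.4-fold higher. Averaged over the list, the change was 0.24 (0.24 with slide as a block, 0.10 to 0.33 within slides, camera adjusted p = 1.29e-05, adjusted p = 0.00761 with an estimated correlation). Of 27 measured heat shock proteins and chaperones, 5 rose, 0 fell and 22 did not pass, with 5 passing adjusted over the list alone. Hspa1a rose by 2.57 ± 0.45, Hspb1 by 2.16 ± 0.32 and the co-chaperone gene Bag3 by 1.10 ± 0.19. As a group they averaged 0.34 (0.34 with slide as a block, 0.10 to 0.60 within slides, camera adjusted p = 0.000706, adjusted p = 0.219 with an estimated correlation). All of these named members passed (limma, adjusted p from 5.94e-06 to 0.00326).

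Of the 20 measured myelin and oligodendrocyte genes, 11 rose, 0 fell and 9 did not pass, with 18 passing adjusted over the list alone. The myelin protein genes Mobp, Mbp and Mag rose by 2.82 ± 0.70, 2.12 ± 0.46 and 2.06 ± 0.47. For the list the mean was 1.06 (1.06 with slide as a block, 0.10 to 2.22 within slides, camera adjusted p = 1.90e-15, adjusted p = 0.159 with an estimated correlation). Among the 31 measured microglia and macrophage markers, 7 rose, 0 fell and 24 did not pass, with 14 passing adjusted over the list alone. Cd53, of leukocyte surfaces, rose by 0.94 ± 0.19 and the complement gene C1qb by 0.76 ± 0.17. All listed genes averaged 0.39 (0.39 with slide as a block, 0.32 to 0.49 within slides, camera adjusted p = 3.91e-09, adjusted p = 0.23 with an estimated correlation). Of 23 measured reactive astrocyte genes, 7 rose, 1 fell and 15 did not pass, with 12 passing adjusted over the list alone. The membrane protein gene Emp1 rose by 1.12 ± 0.24. Over all members the change averaged 0.59 (0.59 with slide as a block, 0.41 to 0.80 within slides, camera adjusted p = 3.09e-07, adjusted p = 0.0682 with an estimated correlation). Mobp, Mbp, Mag, Cd53, C1qb and Emp1 passed (limma, adjusted p from 0.0011 to 0.00839). On HI 1 to 4 the myelin list lay at 1.07, 1.96, 0.60 and 0.63, and the thalamic, hypothalamic and midbrain markers at 1.02, 1.21, -1.56 and -1.55, against -1.36, -0.57, 1.35 and 0.58 on Sham 1 to 4. These markers differed on average by -0.22 (camera p = 0.38, p = 0.824 with an estimated correlation), and by -0.69 to 0.23 with 1 array left out.

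In all 714 genes changed at 3 h after HI (limma), 347 higher and 367 lower, with 82 at 2-fold or more, of which 75 rose and 7 fell. The deposited ratios split the calls 426 higher to 233 lower. The count was 1182 with slide as a block, 64 with only these arrays fitted, 2626 with array weights, 338 with close arrays averaged. Genes were named where the arrays of both groups did not overlap, which chance gives for 2.9% of genes with 4 against 4 arrays and 5.7% with 3 against 4. The count became 386 without Sham 1, 470 without Sham 2, 391 without HI 3, 379 without HI 4. With 1 array left out, calls were lost (highest adjusted p) for Mobp without Sham 1 or HI 2 (0.0617), Mag without Sham 1 (0.0555).

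**Figure D2:**
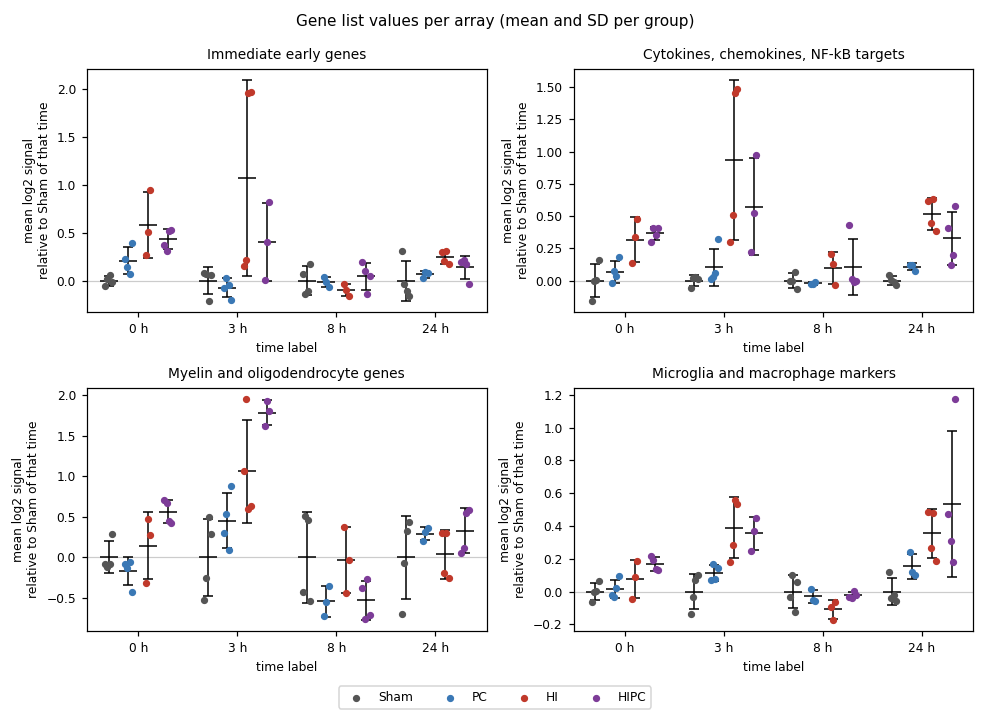
Mean log2 signal of 4 gene lists on each array, relative to the Sham mean of the same time label, with points for arrays coloured by treatment and bars for the mean and SD of 3 or 4 arrays. At 3 h the immediate early genes lay at 0.15, 0.21, 1.95 and 1.97 on the 4 HI arrays.

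At 8 h few genes stood apart from Sham (n = 3 HI and 4 Sham). Acer2 rose by 1.44 ± 0.26 and the metallothionein gene Mt1 by 0.96 ± 0.18 on the log2 scale (limma, adjusted p = 0.0123 for both). Aoc2, an amine oxidase, was at least 1.26-fold higher (adjusted p = 0.0287), and Slc25a36, a mitochondrial carrier of pyrimidine nucleotides, rose by 0.48 ± 0.10 (adjusted p = 0.0381). None of the 16 panel genes passed, and their changes lay from -1.04 to 0.76. Of the 27 measured glucocorticoid-responsive genes, 1 rose, 0 fell and 26 did not pass, with 6 passing adjusted over the list alone. A mean change was measured of 0.30 (0.28 with slide as a block, 0.10 to 0.51 within slides, camera adjusted p = 0.000256, adjusted p = 0.325 with an estimated correlation). These 4 rises and 0 falls stood beside 877 genes with an unadjusted p under 0.05 and a count of 17 with slide as a block (9 higher, 8 lower), 2 with only these arrays fitted, 30 with array weights, 10 with region markers as covariates. With median scaling and in the deposited ratios 0 genes passed. Leaving out 1 array gave counts of 1 without Sham 3, 0 without Sham 4, 2 without HI 1, 0 without HI 2, 23 without HI 3. Lost calls on leaving out 1 array (highest adjusted p) were Acer2 without Sham 4 or HI 2 (0.213), Mt1 without Sham 3/4 or HI 1/2 (0.213), Aoc2 without Sham 3/4 or HI 1/2/3 (0.213), Slc25a36 without Sham 1/2/3/4 or HI 1/2 (0.353).

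At 24 h after HI, Gfap, Spp1 and Ms4a6d were among the genes that rose over Sham, and Slc3a2, Ssb and Pcna among those that fell (n = 4 and 4). Gfap, the astrocyte filament protein, rose by 1.86 ± 0.26 on the log2 scale, Spp1, which encodes osteopontin, by 2.61 ± 0.69, the chemokine gene Ccl12 by 2.01 ± 0.28 and the macrophage gene Ms4a6d by 2.12 ± 0.27 (limma, adjusted p from 1.14e-07 to 0.00464). The sulfotransferase gene Sult1a1 rose by 2.20 ± 0.26, the inositol phosphate kinase gene Ip6k2 by 1.84 ± 0.24, Lmtk3 by 1.75 ± 0.20 and the myosin light chain gene Myl6b by 1.72 ± 0.23 (limma, adjusted p from 2.45e-08 to 3.50e-07). Slc3a2, the heavy chain of amino acid transporters, fell by 1.79 ± 0.21, Ssb, the La RNA-binding protein, by 1.78 ± 0.26, the splicing gene Scnm1 by 1.65 ± 0.23, the replication clamp Pcna by 1.54 ± 0.29, the cohesin gene Rad21 by 1.50 ± 0.24 and Ift57, of intraflagellar transport, by 1.46 ± 0.18 (limma, adjusted p from 3.33e-08 to 8.53e-05). Slc3a2 was also among the 8 genes named for time in Sham. On the first principal component Sham lay from -57.2 to -42.3 at 24 h, apart from HI (-38.8 to -34.7) and PC (-41.6 to -35.9). HIPC lay from -42.9 to -39.3. A shift along this axis of time or batch stays open for its falls here and in PC and HIPC. Lcn2 was at least 6.16-fold higher (adjusted p = 0.0012). Gfap was 1 of 3 panel genes that passed, and the other 13 lay from -1.67 to 1.91.

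Among the 31 measured microglia and macrophage markers, 13 rose, 2 fell and 16 did not pass, with 18 passing adjusted over the list alone. Ly86 rose by 1.28 ± 0.18, the Fc receptor chain gene Fcer1g by 1.22 ± 0.20 and the complement gene C1qc by 1.18 ± 0.18, and P2ry12, the ADP receptor of resting microglia, fell by 1.38 ± 0.21. The list averaged 0.35 (0.35 with slide as a block, 0.34 to 0.37 within slides, camera adjusted p = 0.000648, adjusted p = 0.518 with an estimated correlation, 0.21 in the deposited ratios). Of 33 measured cytokine, chemokine and NF-kB target genes, 12 rose, 0 fell and 21 did not pass, with 15 passing adjusted over the list alone. The chemokine gene Ccl9 rose by 1.12 ± 0.32. These genes averaged 0.52 (0.52 with slide as a block, 0.51 to 0.53 within slides, camera adjusted p = 7.94e-05, adjusted p = 0.436 with an estimated correlation). Of the 23 measured reactive astrocyte genes, 7 rose, 0 fell and 16 did not pass, with 9 passing adjusted over the list alone. The protease inhibitor gene Timp1 rose by 1.57 ± 0.38. Their mean change was 0.49 (0.49 with slide as a block, 0.48 to 0.51 within slides, camera adjusted p = 0.0104, adjusted p = 0.409 with an estimated correlation). Among the 36 measured pan-neuronal and synaptic genes, 6 rose, 8 fell and 22 did not pass, with 15 passing adjusted over the list alone. Slc12a5, the neuronal chloride exporter, fell by 1.78 ± 0.34 and Vamp2, of synaptic vesicles, by 0.91 ± 0.11, while Syn1, also of synaptic vesicles, rose by 0.71 ± 0.11. On average they changed by -0.0087 (-0.0087 with slide as a block, -0.028 to 0.011 within slides, camera adjusted p = 0.613, adjusted p = 0.903 with an estimated correlation). It was 0.016 without Sham 1. Named members of these lists passed throughout (limma, adjusted p from 2.45e-08 to 0.00972). On HI 1 to 4 the microglia list lay at 0.49, 0.27, 0.48 and 0.19, the cytokine list at 0.61, 0.45, 0.63 and 0.38, and the cortical excitatory neuron markers at 0.44, 0.96, 0.42 and 0.70. HI 1 and 3 were the closest pair of the group, and each slide held 1 of them, so values within slides hide this split.

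In all 2286 genes changed at 24 h after HI (limma), 1259 higher and 1027 lower, with 180 at 2-fold or more. The deposited ratios turned this split round, to 847 higher and 1450 lower. Another probe of the gene changed the other way, by any amount, for 272 of the 670 called genes with several probes. The count was 3056 with slide as a block, 1112 with only these arrays fitted, 5435 with array weights. Fitted within slide 13 it was 1376 and within slide 14 it was 118. Without HI 2 the count was 1519. With the brain region markers as covariates it was 1190, of which 1041 were among the 2286.

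The effect of HI over Sham differed between times for 1567 genes (limma F test over the 4 times). Relative to the HI effect at 0 h, the effect at 24 h was higher by 1.75 on the log2 scale for Bcl9l, a beta-catenin cofactor, by 1.84 for Mtss2 and by 1.30 for the chloride channel gene Ttyh3. It was higher by 1.22 for the corepressor gene Atn1, by 1.25 for the G protein subunit gene Gnai2, by 1.16 for Fam114a2 and by 0.75 for Aftph. For the ubiquitin ligase gene Fbxo44 it decreased by 1.11 (adjusted p from 9.48e-09 to 8.06e-07). At 3 h the same differences for these genes lay between -0.49 for Atn1 and 0.04 for Fbxo44. Taken in pairs, the HI effect differed between 3 and 24 h for 1678 genes, 999 higher and 679 lower at 24 h, between 8 and 24 h for 800 (411 higher, 389 lower) and between 3 and 8 h for 206 (133 higher, 73 lower at 8 h). An unadjusted p under 0.05 was found for 3194 genes, 2446 passed with slide as a block, 1033 when only the arrays compared were fitted, 5277 with array weights, 884 with close arrays averaged, 917 with the region markers as covariates, and 1010 without HI 2 of 24 h.

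Preconditioning alone raised 4 genes over Sham at 0 h (n = 4 and 4). Depp1 rose by 2.44 ± 0.33 on the log2 scale, the transcriptional repressor gene Hic1 by 0.83 ± 0.16, P4ha1, a collagen prolyl hydroxylase, by 0.73 ± 0.15 and Farsa, a phenylalanyl-tRNA synthetase subunit, by 0.64 ± 0.13 (limma, adjusted p from 1.79e-05 to 0.0408). None of the 16 panel genes passed, and their changes lay from -1.48 to 0.63. Of 16 measured choroid plexus and ependymal markers, 0 passed singly and 0 adjusted over the list alone. The mean of the list was -0.54 (-0.54 with slide as a block, -1.62 to 0.93 within slides, camera adjusted p = 6.29e-06, adjusted p = 0.397 with an estimated correlation). Without Sham 1 or PC 2/3 it was -0.87 to -0.33. No gene fell (0, limma), 420 had an unadjusted p under 0.05, and the count was 10 with slide as a block, 1 with only these arrays fitted, 16 with array weights, 2 with close arrays averaged, 1 with region markers as covariates. Single arrays left out moved it to 2 without Sham 1, 1 without Sham 3, 2 without Sham 4, 2 without PC 2, 1 without PC 4. Hic1, P4ha1 and Farsa did not pass with region markers as covariates, at 0.78 ± 0.16, 0.78 ± 0.16 and 0.52 ± 0.13 (adjusted p from 0.0575 to 0.25). Calls were lost (highest adjusted p) for Hic1 without Sham 1/3 or PC 4 (0.144), P4ha1 without Sham 2/3/4 or PC 1/2/4 (0.346), Farsa without Sham 1/3/4 or PC 2/3/4 (0.421).

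At 3 h no gene passed for PC against Sham (n = 4 and 4). The count was 0 (limma, smallest adjusted p = 0.369), with 927 genes at an unadjusted p under 0.05, 0 with slide or replicate number as a block, 873 with array weights, and 3 without Sham 3. Slc2a1, at 0.55 ± 0.16, and Cdkn1a, a p53-induced inhibitor of the cell cycle, at 0.66 ± 0.20, did not pass (adjusted p = 0.622 for both), and the 16 panel genes lay from -0.95 to 0.98. Of the 20 measured myelin and oligodendrocyte genes, 0 passed singly and 0 adjusted over the list alone. Together these genes averaged 0.45 (0.45 with slide as a block, -0.41 to 0.83 within slides, camera adjusted p = 1.88e-06, adjusted p = 0.436 with an estimated correlation, 0.13 with region markers as covariates with adjusted p = 0.0793). It was 0.28 without Sham 1. Among the 14 measured cortical excitatory neuron markers, 0 passed singly and 2 adjusted over the list alone. The listed genes averaged -0.71 (-0.71 with slide as a block, -1.15 to -0.27 within slides, camera adjusted p = 3.12e-06, adjusted p = 0.166 with an estimated correlation). Beside these lists the thalamic, hypothalamic and midbrain markers differed by 0.95 (camera p = 5.46e-14, p = 0.0613 with an estimated correlation), and by 0.50 without Sham 1.

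At 8 h 0 genes passed for PC (n = 3 PC and 4 Sham, limma, smallest adjusted p = 0.0673), with 682 at an unadjusted p under 0.05, 1 with slide as a block, 3 with replicate number as a block, 1 with only these arrays fitted, 46 with array weights. Hmox1, the heme-degrading enzyme, lay at 0.95 ± 0.32 (adjusted p = 0.528), and the panel from -0.97 to 1.81. Of 20 measured myelin and oligodendrocyte genes, 0 passed singly and 0 adjusted over the list alone. Averaged over the list, the change was -0.55 (-0.50 with slide as a block, -1.02 to 0.20 within slides, camera adjusted p = 1.32e-07, adjusted p = 0.409 with an estimated correlation). The count became 1 without Sham 3, 2 without Sham 4, 3 without PC 1, 4 without PC 2, 1 without PC 3.

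At 24 h in PC, Ssb, Rad21 and Slc3a2 were among the genes that fell below Sham, and Gstm2, Slc6a12 and Lyz1 among those that rose (n = 3 PC and 4 Sham). Ssb fell by 1.64 ± 0.28 on the log2 scale, Rad21 by 1.59 ± 0.26, Ccni, a cyclin family gene, by 1.42 ± 0.27 and Slc3a2 by 1.25 ± 0.23, and the ubiquitin-conjugating gene Ube2v2 was at least 2.03-fold lower (limma, adjusted p from 7.14e-06 to 0.000958). Pcna fell by 1.27 ± 0.31, the proton pump subunit Atp6v0c by 1.42 ± 0.35 and the ADP/ATP carrier Slc25a4 by 1.14 ± 0.30. The glutathione transferase gene Gstm2 rose by 1.00 ± 0.18, Slc6a12, a betaine and GABA transporter, by 1.45 ± 0.34 and the lysozyme gene Lyz1 by 1.21 ± 0.27 (limma, adjusted p from 0.000725 to 0.0307). The same 4 Sham arrays served for HI, PC and HIPC at 24 h. No panel gene passed, and the 16 lay from -0.57 to 2.08, with the choroid plexus transthyretin gene Ttr at 2.08 ± 1.50 (adjusted p = 0.74). Of the 16 measured choroid plexus and ependymal markers, 0 passed singly and 0 adjusted over the list alone. As a group they averaged 0.75 (0.69 with slide as a block, 0.64 to 0.73 within slides, camera adjusted p = 0.000825, adjusted p = 0.511 with an estimated correlation). Without PC 1 it was 0.47 (adjusted p = 0.191).

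In all 211 genes changed at 24 h in PC (limma), 58 higher and 153 lower, against 41 higher and 248 lower in the deposited ratios. The count was 359 with slide as a block, 0 with only these arrays fitted, 2045 with array weights, 66 with close arrays averaged. Within slide 13 and within slide 14 it was 0, with 2 PC arrays on the first and 1 on the second. Without 1 array the count was 97 and 49 (Sham 3, 4), 135, 56 and 125 (PC 1 to 3). With 1 array left out, calls were lost (highest adjusted p) for Pcna and Atp6v0c and Slc25a4 without Sham 3/4 or PC 1/2 (0.224 and 0.258 and 0.302), Slc6a12 without Sham 4 or PC 2/3 (0.211), Lyz1 without Sham 4 or PC 2 (0.179).

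In pups with PC and HI, Depp1, Edn1, Fos and S100a8 were among the genes that rose over Sham at 0 h (n = 4 and 4). Depp1 rose by 2.98 ± 0.33 on the log2 scale, Ier3 by 1.72 ± 0.24, Edn1 by 1.63 ± 0.28, Fos by 2.26 ± 0.50, S100a8 by 2.35 ± 0.51 and Cstdc4 by 1.68 ± 0.33, and Lcn2 was at least 6.63-fold higher (limma, adjusted p from 6.46e-08 to 0.028). Red blood cell genes lay at 0.484 to 0.665 on HIPC and -0.114 to 0.139 on Sham arrays. Among the 6 falls, Aif1l fell by 0.54 ± 0.13 (adjusted p = 0.0411). Fos and Slc2a1, at 0.81 ± 0.16 (adjusted p = 0.0095), were the 2 panel genes that passed, and the other 14 lay from -2.28 to 1.17. Among the 27 measured glucocorticoid-responsive genes, 4 rose, 0 fell and 23 did not pass, with 12 passing adjusted over the list alone. The transcription factor gene Cebpb rose by 1.01 ± 0.20 (adjusted p = 0.0076). For the list the mean was 0.46 (0.46 with slide as a block, 0.38 to 0.54 within slides, camera adjusted p = 3.11e-15, adjusted p = 0.00785 with an estimated correlation). Of 40 measured hypoxia and HIF targets, 1 rose, 0 fell and 39 did not pass, with 6 passing adjusted over the list alone. All listed genes averaged 0.14 (0.14 with slide as a block, 0.092 to 0.22 within slides, camera adjusted p = 0.00107, adjusted p = 0.0409 with an estimated correlation). Of the 16 measured choroid plexus and ependymal markers, 0 passed singly and 4 adjusted over the list alone. Over all members the change averaged -0.81 (-0.81 with slide as a block, -1.32 to 0.22 within slides, camera adjusted p = 1.40e-07, adjusted p = 0.297 with an estimated correlation).

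In all 30 genes rose and 6 fell at 0 h in HIPC (limma), 865 had an unadjusted p under 0.05, and the count was 69 with slide as a block, 22 with only these arrays fitted, 205 with array weights, 14 with close arrays averaged, 20 with sex as a covariate. Median scaling gave 34 higher and 2 lower, and the deposited ratios 31 higher and 0 lower. Without slide 1, 21 genes passed. The count was 16 without Sham 2, Sham 3 or HIPC 4, 17 without HIPC 1 and 19 without HIPC 2 or 3. Lost without 1 array (highest adjusted p) were Fos without Sham 2/3/4 or HIPC 1/3/4 (0.139) and Lcn2 without any 1 array (0.107). S100a8 was lost without any 1 but Sham 4 (0.131) and Aif1l without any 1 but Sham 1 (0.175).

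At 3 h in HIPC, Mobp, Mbp and Fos were among the genes that rose over Sham, and Dcx and Nes among those that fell (n = 3 HIPC and 4 Sham). The myelin protein genes Mobp, Mag, Mbp and Mog rose by 4.31 ± 0.76, 3.17 ± 0.51, 2.98 ± 0.50 and 2.80 ± 0.51 on the log2 scale, and Pvalb, the calcium-binding parvalbumin of fast-spiking neurons, by 2.77 ± 0.60 (limma, adjusted p from 4.71e-05 to 0.00157). Fos rose by 3.06 ± 0.54 and Ccl4 by 3.23 ± 0.78, Fosb was at least 4.15-fold and Lcn2 at least 5.89-fold higher (limma, adjusted p from 0.000108 to 0.00519). Dcx fell by 1.97 ± 0.29, Akr1c19 by 1.47 ± 0.23, the RNA-binding gene Mex3a by 1.46 ± 0.25, the hyaluronan synthase gene Has3 by 1.45 ± 0.31 and the intermediate filament gene Nes by 1.21 ± 0.21 (limma, adjusted p from 1.18e-05 to 0.00128). Gfap, at 1.20 ± 0.28, was 1 of 7 panel genes that passed (adjusted p = 0.00317), and the other 9 lay from -1.98 to 1.74.

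Among the 20 measured myelin and oligodendrocyte genes, 18 rose, 0 fell and 2 did not pass, with 19 passing adjusted over the list alone. A mean change was measured of 1.79 (1.71 with slide as a block, 1.43 to 1.88 within slides, camera adjusted p = 6.24e-25, adjusted p = 0.0409 with an estimated correlation). Of 23 measured homeostatic astrocyte markers, 10 rose, 0 fell and 13 did not pass, with 12 passing adjusted over the list alone. Gjb6 rose by 1.88 ± 0.25 and the neurotensin receptor gene Ntsr2 by 1.63 ± 0.24. The list averaged 0.59 (0.57 with slide as a block, 0.25 to 0.80 within slides, camera adjusted p = 3.39e-08, adjusted p = 0.156 with an estimated correlation, 0.32 with region markers as covariates). With the covariates 7 astrocyte genes passed, 6 of them among the 10. Of the 27 measured glucocorticoid-responsive genes, 11 rose, 0 fell and 16 did not pass, with 16 passing adjusted over the list alone. Sult1a1 rose by 1.53 ± 0.28 and the phagocytic receptor gene Mertk by 1.41 ± 0.22. These genes averaged 0.67 (0.64 with slide as a block, 0.61 to 0.73 within slides, camera adjusted p = 1.85e-10, adjusted p = 0.0409 with an estimated correlation). Among the 40 measured hypoxia and HIF targets, 11 rose, 0 fell and 29 did not pass, with 17 passing adjusted over the list alone. Slc2a1 rose by 1.26 ± 0.18. Their mean change was 0.28 (0.27 with slide as a block, 0.22 to 0.34 within slides, camera adjusted p = 2.47e-05, adjusted p = 0.00761 with an estimated correlation). Of 14 measured cortical excitatory neuron markers, 1 rose, 3 fell and 10 did not pass, with 8 passing adjusted over the list alone. On average they changed by -0.73 (-0.75 with slide as a block, -1.25 to 0.31 within slides, camera adjusted p = 0.0122, adjusted p = 0.493 with an estimated correlation). Of the 16 measured subventricular zone neuroblast genes, 0 rose, 3 fell and 13 did not pass, with 3 passing adjusted over the list alone. The mean of the list was -0.50 (-0.45 with slide as a block, -0.65 to 0.029 within slides, camera adjusted p = 0.00131, adjusted p = 0.296 with an estimated correlation, -0.29 with region markers as covariates). The named members passed (limma, adjusted p from 2.61e-06 to 0.000271). Beside the myelin, astrocyte and cortical lists, the thalamic, hypothalamic and midbrain markers were displaced by 1.17 (camera p = 4.81e-08, p = 0.171 with an estimated correlation), and by 0.72 without Sham 1.

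Among the 35 measured immediate early genes, 9 rose, 2 fell and 24 did not pass, with 12 passing adjusted over the list alone. Together these genes averaged 0.41 (0.31 with slide as a block, -0.062 to 0.76 within slides, camera adjusted p = 0.0199, adjusted p = 0.802 with an estimated correlation, adjusted p = 0.0678 with the block, 0.80 with region markers as covariates). It was 0.20 to 0.34 (highest adjusted p = 0.333) without Sham 3 or HIPC 3. Of these genes 15 passed with the covariates, 7 of them among the 11. Of 33 measured cytokine, chemokine and NF-kB target genes, 7 rose, 0 fell and 26 did not pass, with 9 passing adjusted over the list alone. Tnfrsf12a rose by 1.97 ± 0.36. The listed genes averaged 0.57 (0.48 with slide as a block, 0.20 to 0.96 within slides, camera adjusted p = 2.17e-05, adjusted p = 0.409 with an estimated correlation). Without HIPC 3 it was 0.37. Tnfrsf12a passed (limma, adjusted p = 0.000252). In all 710 genes rose and 679 fell (limma), 175 by 2-fold or more, and the count was 1599 with slide as a block, 3363 with array weights. With the region markers as covariates 775 passed, 603 of them among the 1389. The count became 627 without Sham 1, 838 without Sham 2, 797 without HIPC 1, 641 without HIPC 3. Calls were lost (highest adjusted p) for Ccl4 without HIPC 3 (0.13).

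At 8 h in HIPC, Acer2 rose by 1.57 ± 0.24 and Mt1 by 0.81 ± 0.16 on the log2 scale over Sham (n = 4 and 4, limma, adjusted p = 0.000516 and 0.0398). The dim genes Ccdc27 and Tcl1b3 were at least 1.14-fold and at least 1.08-fold higher, and the DNA repair gene Mgmt was at least 1.07-fold lower (limma, adjusted p from 0.0126 to 0.0398). No bound could be set for Dsg1b (adjusted p = 0.0398). None of the 16 panel genes passed, and they lay from -1.12 to 1.59. Of the 27 measured glucocorticoid-responsive genes, 1 rose, 0 fell and 26 did not pass, with 4 passing adjusted over the list alone. Averaged over the list, the change was 0.33 (0.33 with slide as a block, 0.16 to 0.65 within slides, camera adjusted p = 4.08e-06, adjusted p = 0.188 with an estimated correlation). It was 0.21 without HIPC 1. Among the 32 measured striatal projection neuron genes, 0 passed singly and 0 adjusted over the list alone. As a group they averaged 0.45 (0.45 with slide as a block, 0.0042 to 1.14 within slides, camera adjusted p = 2.56e-08, adjusted p = 0.325 with an estimated correlation). Without HIPC 2 it was 0.29. These 5 rises and 1 fall became 22 changes with slide as a block and 12 with replicate number as a block, where replicate numbers paired the arrays and Dsg1b did not pass (adjusted p = 0.0515), and 1 rise and 0 falls with median scaling. In the deposited ratios 0 passed, the count was 1 with only these arrays fitted, 12 with array weights, 2 with sex as a covariate, and 845 genes had an unadjusted p under 0.05. Leaving out 1 array gave counts of 1 without Sham 2, 3 without Sham 3, 2 without Sham 4, 2 without HIPC 1, 2 without HIPC 2. Mgmt and Dsg1b did not pass with region markers as covariates, at -0.43 ± 0.11 and 0.34 ± 0.088 (adjusted p from 0.142 to 0.164). With 1 array left out, calls were lost (highest adjusted p) for Mt1 without Sham 2/3/4 or HIPC 1/2 (0.194), Ccdc27 without Sham 1/2 or HIPC 4 (0.11), Tcl1b3 without Sham 2/4 or HIPC 1/2/3 (0.237), Mgmt without Sham 2/3/4 or HIPC 1/2/3/4 (0.2), Dsg1b without Sham 1/2/3/4 or HIPC 1/2/4 (0.175).

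At 24 h in HIPC, S100a8, Stfa1 and Ms4a6d were among the genes that rose over Sham, and Atp6v0c, Ssb and Cck among those that fell (n = 4 and 4). S100a8 rose by 2.21 ± 0.51 on the log2 scale, Stfa1 by 1.89 ± 0.51, Sult1a1 by 1.86 ± 0.26, Ms4a6d by 1.64 ± 0.27, the surface antigen gene Ly6a by 1.60 ± 0.23, the serpin gene Serpina3n by 1.56 ± 0.30 and Lyz1 by 1.55 ± 0.25 (limma, adjusted p from 9.37e-07 to 0.00549). Atp6v0c fell by 1.72 ± 0.32, Ssb by 1.56 ± 0.26, Ccni by 1.49 ± 0.25, Slc3a2 by 1.43 ± 0.21, the ubiquitin ligase gene Nedd4 by 1.35 ± 0.16, the neuropeptide gene Cck by 1.32 ± 0.22 and Ube2v2 by 1.29 ± 0.16 (limma, adjusted p from 3.28e-08 to 9.66e-05). Eif2s3y, on the Y chromosome, was at least 7.4-fold lower (adjusted p = 0.0231), where HIPC held 0 males and Sham 3. Slc2a1, at 0.72 ± 0.16, and Aif1, a microglial calcium-binding protein, at 1.07 ± 0.16, were the 2 panel genes that passed (adjusted p = 0.00104 and 3.49e-06), and the other 14 lay from -0.53 to 2.68.

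Of 31 measured microglia and macrophage markers, 18 rose, 0 fell and 13 did not pass, with 20 passing adjusted over the list alone. Ly86 rose by 1.42 ± 0.18 and Lyz2 by 1.32 ± 0.27. For the list the mean was 0.54 (0.54 with slide as a block, 0.35 to 0.72 within slides, camera adjusted p = 2.31e-07, adjusted p = 0.325 with an estimated correlation, 0.28 in the deposited ratios). It was 0.32 without HIPC 4. Of the 36 measured pan-neuronal and synaptic genes, 1 rose, 12 fell and 23 did not pass, with 15 passing adjusted over the list alone. Dlg4, a postsynaptic scaffold gene, fell by 0.69 ± 0.14, Stx1a by 0.59 ± 0.12 and Syt1 by 0.46 ± 0.10. All listed genes averaged -0.20 (-0.20 with slide as a block, -0.25 to -0.15 within slides, camera adjusted p = 0.000365, adjusted p = 0.228 with an estimated correlation). Among the 32 measured striatal projection neuron genes, 10 rose, 0 fell and 22 did not pass, with 12 passing adjusted over the list alone. Over all members the change averaged 0.61 (0.61 with slide as a block, 0.33 to 0.88 within slides, camera adjusted p = 0.0146, adjusted p = 0.75 with an estimated correlation). Without HIPC 1/2 it was 0.45 to 0.49 (highest adjusted p = 0.131). The members named passed (limma, adjusted p from 8.10e-08 to 0.000497). In all 1468 genes rose and 1084 fell (limma), 94 by 2-fold or more, while the deposited ratios gave 1133 higher and 2024 lower. The count was 3436 with slide as a block, 1370 with only these arrays fitted, 4495 with array weights, 1470 within slide 13 and 1 within slide 14. Lost calls on leaving out 1 array (highest adjusted p) were Eif2s3y without Sham 2/3/4 (0.0815).

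HIPC against HI asks whether preconditioning altered the response. At 0 h the count was 0 (n = 4 HIPC and 3 HI, limma, smallest adjusted p = 0.203), with 415 genes at an unadjusted p under 0.05 and 0 with slide or replicate number as a block. The 16 panel genes lay from -1.26 to 0.96, with Fos at -0.038 ± 0.54.

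At 3 h, 1 gene differed between HIPC and HI, the tissue kallikrein gene Klk1, higher by 1.16 ± 0.19 on the log2 scale on all 3 slides (n = 3 HIPC and 4 HI, limma, adjusted p = 0.00209). Fos, at -0.80 ± 0.54, did not pass (adjusted p = 0.66), and the panel lay from -2.55 to 1.57. Of 35 measured immediate early genes, 0 passed singly and 15 adjusted over the list alone. The mean was -0.66 (-0.76 with slide as a block, -1.55 to -0.21 within slides, camera adjusted p = 2.93e-16, adjusted p = 0.194 with an estimated correlation, -0.12 with region markers as covariates). It was -0.37 to -0.36 without HI 3/4. Of the 20 measured myelin and oligodendrocyte genes, 0 passed singly and 7 adjusted over the list alone. The list averaged 0.72 (0.65 with slide as a block, -0.33 to 1.34 within slides, camera adjusted p = 1.33e-11, adjusted p = 0.267 with an estimated correlation, 0.20 with region markers as covariates). Among the 33 measured cytokine, chemokine and NF-kB target genes, 0 passed singly and 2 adjusted over the list alone. These genes averaged -0.36 (-0.45 with slide as a block, -0.93 to -0.28 within slides, camera adjusted p = 4.08e-06, adjusted p = 0.397 with an estimated correlation, -0.19 with region markers as covariates). Without HI 1/3/4 or HIPC 1/3 it was -0.57 to -0.18. Beside these lists the thalamic, hypothalamic and midbrain markers differed by 1.39 (camera p = 2.22e-19, p = 0.0263 with an estimated correlation). At an unadjusted p under 0.05 there were 1208 genes, the count was 2 with slide as a block, 0 with only these arrays fitted, 3034 with array weights, 3 with sex as a covariate, and 4 were higher and 1 lower with median scaling, as in the deposited ratios. With 1 array left out it was 34 (HI 1), 330 (HI 2), 0 (HI 3 or HIPC 1), 2 (HIPC 2) and 6 (HIPC 3). Klk1 did not pass with region markers as covariates, at 0.81 ± 0.19 (adjusted p = 0.615). Calls were lost (highest adjusted p) for Klk1 without HI 3 or HIPC 1 (0.169).

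At 8 h the cAMP-responsive transcription factor gene Crem was higher in HIPC than in HI by 0.84 ± 0.16 on the log2 scale (n = 4 HIPC and 3 HI, limma, adjusted p = 0.034), on all 3 slides, and no other gene passed. The 16 panel genes lay from -1.01 to 2.64. An unadjusted p under 0.05 was found for 477 genes, 2 passed with slide as a block (1 higher, 1 lower), and 0 did with median scaling or in the deposited ratios. The count became 0 without HI 1/2 or HIPC 1/2/4. Crem did not pass with region markers as covariates, at 0.77 ± 0.16 (adjusted p = 0.163). With 1 array left out, calls were lost (highest adjusted p) for Crem without HI 1/2 or HIPC 1/2/4 (0.587).

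At 24 h, Gsk3a, Myl6b and Gal3st3 were among the genes lower in HIPC than in HI, and Slc35d3 and Asb2 among those higher (n = 4 and 4). Slc17a7, the vesicular glutamate transporter of cortical neurons, was lower, at -3.18 ± 0.73 on the log2 scale, Nrgn, a postsynaptic calmodulin-binding protein, at -1.95 ± 0.57, the kinase gene Gsk3a at -1.88 ± 0.20, Myl6b at -1.86 ± 0.23, the sulfotransferase gene Gal3st3 at -1.70 ± 0.21 and Gfap at -1.24 ± 0.26 (limma, adjusted p from 3.24e-09 to 0.0108). Slc35d3 was higher by 1.75 ± 0.28, the ubiquitin ligase adaptor genes Asb2 and Asb4 by 1.51 ± 0.25 and 1.25 ± 0.30, and P2ry12 by 0.99 ± 0.21 (limma, adjusted p from 1.13e-05 to 0.00211). Gfap was 1 of 3 panel genes that passed, and the other 13 lay from -0.30 to 3.66, with Ttr at 3.66 ± 1.40 (adjusted p = 0.0509).

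Of 14 measured cortical excitatory neuron markers, 0 were higher, 7 were lower and 7 did not pass, with 8 passing adjusted over the list alone. Their mean change was -0.99 (-0.99 with slide as a block, -1.11 to -0.88 within slides, camera adjusted p = 0.000706, adjusted p = 0.362 with an estimated correlation). Of the 32 measured striatal projection neuron genes, 5 were higher, 0 were lower and 27 did not pass, with 5 passing adjusted over the list alone. The signalling regulator gene Rgs9 was higher by 1.39 ± 0.30 and the opioid peptide gene Pdyn by 1.07 ± 0.24. On average they changed by 0.48 (0.48 with slide as a block, 0.12 to 0.84 within slides, camera adjusted p = 0.0271, adjusted p = 0.789 with an estimated correlation, adjusted p = 0.0532 with the block). It was 0.33 to 0.75 (highest adjusted p = 0.176) without HI 4 or HIPC 1/2/4. Among the 33 measured cell cycle genes, 11 were higher, 0 were lower and 22 did not pass, with 12 passing adjusted over the list alone. The mitotic kinase gene Plk1 was higher by 0.90 ± 0.25. The mean of the list was 0.39 (0.39 with slide as a block, 0.11 to 0.67 within slides, camera adjusted p = 0.00511, adjusted p = 0.798 with an estimated correlation, 0.25 in the deposited ratios). Without HIPC 4 it was 0.10 (adjusted p = 0.645). Of 31 measured microglia and macrophage markers, 9 were higher, 0 were lower and 22 did not pass, with 9 passing adjusted over the list alone. P2ry13, a purine receptor gene, was higher by 0.87 ± 0.17 and Gpr34 by 0.98 ± 0.19. Together these genes averaged 0.18 (0.18 with slide as a block, 0.013 to 0.34 within slides, camera adjusted p = 0.149, adjusted p = 0.879 with an estimated correlation). It was -0.035 without HIPC 4 and it passed without HI 1/3 or HIPC 2/3 (highest adjusted p = 0.0449). Of the 36 measured pan-neuronal and synaptic genes, 3 were higher, 10 were lower and 23 did not pass, with 17 passing adjusted over the list alone. Dlg4 was lower, at -0.56 ± 0.14, as was the tau gene Mapt, at -0.62 ± 0.11. The listed genes averaged -0.19 (-0.19 with slide as a block, -0.26 to -0.12 within slides, camera adjusted p = 0.0107, adjusted p = 0.409 with an estimated correlation, -0.086 with region markers as covariates with adjusted p = 0.0716, -0.16 in the deposited ratios with adjusted p = 0.172). It was -0.14 (adjusted p = 0.103) without HIPC 4. The members named passed (limma, adjusted p from 4.18e-05 to 0.00652). With region markers as covariates 62 of 89 named genes did not pass. They include Slc17a7 (-0.58 ± 0.28), Nrgn, Gfap (-0.82 ± 0.30), Asb4, P2ry12, Pdyn, Plk1, Dlg4 and Mapt (adjusted p from 0.0504 to 0.745). Cortical genes are among the markers.

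In all 1414 genes were higher and 1342 lower in HIPC than in HI at 24 h (limma), and at 2-fold or more 13 were higher and 92 lower. The deposited ratios gave 840 higher and 1407 lower. The count was 3792 with slide as a block, 1258 with only these arrays fitted, 4798 with array weights, 3250 within slide 13 and 1 within slide 14. With the region markers as covariates 1098 passed, of which 911 were among the 2756. Without HIPC 1 the count was 1837.

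A preconditioning by HI interaction, the difference between the HI effect with and without PC, was tested over the 4 times, and 109 genes passed (limma F test, 1189 at an unadjusted p under 0.05). At 24 h the HI effect with PC differed from that without by -0.89 on the log2 scale for the postsynaptic scaffold gene Dlgap4, by -1.29 for Gnai2 and by -1.64 and -1.36 for the retrotransposon-derived genes Rtl8a and Rtl8b. The difference was -1.18 for the septin gene Septin5, -1.38 for Olfm2, -1.31 for the transcription cofactor gene Cited2 and 1.46 for the ubiquitin ligase gene Rnf115 (adjusted p from 0.000405 to 0.00447). For the same 8 genes the differences at 3 h lay between -0.36 for Cited2 and 0.20 for Rtl8b. Tested at each time, 541 genes passed at 24 h and 0 at 0, 3 and 8 h (limma), with 2010 at an unadjusted p under 0.05 at 24 h and 531, 236 and 558 at the other times. The count over all times was 336 with slide as a block, 185 with replicate number as a block, 57 with median scaling, 30 in the deposited ratios, 2376 with array weights, 40 with close arrays averaged and 2 with the region markers as covariates. Without 1 array of 24 h it was 203, 53 and 37 (Sham 1, 3, 4), 58 and 18 (PC 1, 2), 50, 41, 68 and 337 (HI 1 to 4), 60 and 190 (HIPC 1, 4).

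In Sham alone, 9414 of 12470 genes differed between the 4 time labels (limma F test with slide as a random block, correlation 0.168, 9680 at an unadjusted p under 0.05). Golm2 lay 2.86 higher at 3 h, -0.29 at 8 h and 4.62 higher at 24 h than at 0 h on the log2 scale. Gramd4, Rsu1, the topoisomerase gene Top2b, the Golgi scaffold gene Gopc, Slc3a2, the coactivator gene Rbm14 and Pcmtd2 followed the same course, between 1.04 for Slc3a2 and 2.63 for Pcmtd2 at 3 h, and between 2.94 for Gopc and 4.07 for Slc3a2 at 24 h, while at 8 h they lay between -0.23 for Top2b and 0.03 for Pcmtd2 (adjusted p from 1.14e-24 to 6.66e-24). Each slide held 1 time, so time and a batch of array processing shared by the slides of a time cannot be told apart. Sham 1 of 0 h lay at -0.8 on the first principal component, against 46.7 to 50.4 for the other Sham arrays of 0 h. In the deposited ratios this difference is 0 because each Sham mean was set to 1.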

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

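The test of slide on the differences between HIPC and HI at 24 h was chosen after the result was seen. Over 29 lists and 11 groups of 4 arrays, 20 of 319 tests found an array whose gap to the nearest other exceeded the 95% limit as a share of the group's range, where chance gives about 16 (1 in 20). Each is given as that share, with the list's log2 mean on the array against the range of the others. Sham at 0 h, replicate 1, stood apart by 0.888 for heat shock proteins and chaperones (0.21 against -0.090 to -0.056), 0.886 for unfolded protein and amino acid stress response (0.15 against -0.063 to -0.039), 0.881 for striatal projection neuron genes (-0.37 against 0.089 to 0.15). Sham at 0 h, replicate 4, stood apart by 0.857 for metallothionein and antioxidant genes (-0.14 against 0.037 to 0.067) and 0.9 for myelin and oligodendrocyte genes (0.29 against -0.12 to -0.080). HIPC at 0 h, replicate 2, stood apart by 0.941 for glucocorticoid-responsive genes (0.48 against 0.45 to 0.45). HIPC at 0 h, replicate 1, stood apart by 0.83 for mitochondrial respiratory chain genes (0.24 against -0.070 to -0.017). Sham at 3 h, replicate 3, stood apart by 0.908 for immediate early genes (-0.21 against 0.058 to 0.085). Sham at 3 h, replicate 4, stood apart by 0.858 for reactive astrocyte genes (0.11 against -0.049 to -0.027). PC at 3 h, replicate 4, stood apart by 0.865 for cytokines, chemokines and NF-kB targets (0.32 against 0.014 to 0.055). PC at 3 h, replicate 2, stood apart by 0.947 for oligodendrocyte progenitor markers (0.043 against 0.11 to 0.12). HI at 3 h, replicate 2, stood apart by 0.902 for striatal projection neuron genes (-0.40 against 0.20 to 0.27). HI at 3 h, replicate 1, stood apart by 0.926 for cell cycle genes (0.48 against -0.30 to -0.24). Sham at 8 h, replicate 3, stood apart by 0.931 for cell cycle genes (0.33 against -0.13 to -0.10). HIPC at 8 h, replicate 1, stood apart by 0.957 for cytokines, chemokines and NF-kB targets (0.43 against -0.0090 to 0.010), 0.84 for glucocorticoid-responsive genes (0.70 against 0.18 to 0.27), 0.863 for reactive astrocyte genes (0.68 against 0.062 to 0.15). Sham at 24 h, replicate 1, stood apart by 0.919 for striatal projection neuron genes (0.35 against -0.13 to -0.091). HIPC at 24 h, replicate 4, stood apart by 0.839 for immediate early genes (-0.035 against 0.18 to 0.22) and 0.842 for T and B lymphocyte markers (-0.20 against 0.0020 to 0.040).

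The HI effect differed between times for 1567 genes and the interaction of PC and HI passed for 109, both by limma F tests of the difference itself.

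Between HIPC and HI at 24 h 2756 genes differed, and a different share of brain regions in the pieces of tissue may account for a part: with region markers as covariates 0.398 of the count stayed, 1098 genes with 911 of them among the 2756. Gfap went from -1.24 ± 0.26 to -0.82 ± 0.30 (limma, adjusted p = 0.0759), where the fold shrank and its error grew. A shift by sex shared by all groups was argued against (0.997 of the count with sex as a covariate). A response that differs by sex was not tested, since HIPC held 0 males. The test of slide (1.38 of the count with slide as a block) argues nothing, since slides 13 and 14 each held 2 arrays of both groups and a shift of a whole slide cancels between them. An effect of preconditioning and the position on the slide stay open beside region.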

How the results depend on the processing

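Added after seeing data were normexp without detection values, region or sex covariates, averaging close arrays, omitting slide 1 and list tests without 1 array. Of 4482 alternative values of the 501 named gene results, 3941 kept direction and side of the threshold, 537 lost the call and 4 reversed. With 1 array left out, 3092 of 3878 kept both, 786 lost the call and 0 reversed. For the 134 passing lists, 403 of 653 kept both, 248 lost the call and 2 reversed, and with 1 array left out 889 of 1011 kept both, 120 lost the call and 2 reversed. Of all 464 list tests, camera with an estimated correlation passed 10 and the rotation test 56, 47 of them among the 134. Reversed were Tubb2b in HIPC/Sham 24 h (0.019, median scaling), Mapt in HI/Sham 3 h (0.068) and HIPC/Sham 3 h (0.040) and Bbc3 in HIPC/HI 24 h (-0.031), all by the mean of probes, and with region markers as covariates in HIPC/HI 3 h the homeostatic astrocyte (-0.0088) and cholesterol synthesis (0.029) lists. The cell cycle list in HIPC/Sham 0 h ranged from -0.044 to 0.35 with 1 array left out. The cause was not tested. Dim genes are limited by their signal over background.

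Gene counts that moved by over 1.5 times follow, and the cause was not tested. The main fit pooled the spread of all groups. No background correction gave 7 for HI/Sham 8 h, 3 for HIPC/Sham 8 h, 0 for HIPC/HI 3 h, 0 for HIPC/HI 8 h. Median scaling gave 0 for HI/Sham 8 h, 1 for HIPC/Sham 8 h, 5 for HIPC/HI 3 h, 0 for HIPC/HI 8 h, 57 for the interaction. Series matrix values gave 0 for HI/Sham 8 h, 0 for HIPC/Sham 8 h, 5 for HIPC/HI 3 h, 0 for HIPC/HI 8 h, 30 for the interaction and by construction 0 for Sham over time. No detection filter gave 10 for HI/Sham 8 h, 2 for PC/Sham 0 h, 8 for PC/Sham 8 h, 9 for HIPC/HI 8 h. Stricter detection filter gave 1 for HIPC/Sham 8 h. Fitted on only the arrays compared, HI/Sham gave 3, 64, 2 and 1112 at 0, 3, 8 and 24 h. PC/Sham gave 1, 1 and 0, and HIPC/Sham 22, 1 and 1370, at 0, 8 and 24 h. HIPC/HI gave 0 and 1258 at 3 and 24 h, and the HI effect by time 1033. Slide block gave 1182 and 17 for HI/Sham at 3 and 8 h, and 10, 1 and 359 for PC/Sham at 0, 8 and 24 h. HIPC/Sham gave 69 and 22 at 0 and 8 h, HIPC/HI 2 at 3 and 8 h, the HI effect by time 2446, the interaction 336. Replicate block gave 23 for HI/Sham 8 h, 3 for PC/Sham 8 h, 12 for HIPC/Sham 8 h, 3 for HIPC/HI 3 h, 2 for HIPC/HI 8 h, 185 for the interaction. Array weights gave 47, 2626, 30 and 5435 for HI/Sham at 0, 3, 8 and 24 h. At the same times they gave 16, 873, 46 and 2045 for PC/Sham and 205, 3363, 12 and 4495 for HIPC/Sham. They gave 3034, 0 and 4798 for HIPC/HI at 3, 8 and 24 h, 5277 for the HI effect by time, 2376 for the interaction. Normexp without detection values gave the same as no background correction. Region markers as covariates gave 22, 10 and 1190 for HI/Sham at 0, 8 and 24 h, and 0, 0 and 1098 for HIPC/HI at 3, 8 and 24 h. They gave 1 for PC/Sham 0 h, 775 for HIPC/Sham 3 h, 917 for the HI effect by time, 2 for the interaction. Sex as a covariate gave 8 for HI/Sham 0 h, 20 for HIPC/Sham 0 h, 2 for HIPC/Sham 8 h, 3 for HIPC/HI 3 h. Close arrays averaged gave 6 for HI/Sham 0 h, 338 for HI/Sham 3 h, 2 for PC/Sham 0 h, 66 for PC/Sham 24 h, 14 for HIPC/Sham 0 h, 884 for the HI effect by time, 40 for the interaction. Without slide 1 gave 4 for HI/Sham 0 h, 21 for HIPC/Sham 0 h. Outside the comparisons that replicate numbers paired, correlations of same-numbered arrays ranged from -0.558 to 0.712, in no comparison did every sample correlate best with its own number, and the replicate block changed no other count by over 1.5 times.

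Leaving out each array in turn gave 3 to 12, 379 to 1010, 0 to 23 and 1519 to 2789 for HI/Sham at 0, 3, 8 and 24 h. In that order of times it gave 1 to 5, 0 to 3, 0 to 4 and 49 to 276 for PC/Sham. HIPC/Sham gave 16 to 47, 627 to 1916, 1 to 6 and 1996 to 2437, and HIPC/HI 0 to 0, 0 to 330, 0 to 1 and 1837 to 3285. It gave 1010 to 2073 for the HI effect by time, 18 to 337 for the interaction and 9033 to 9525 for Sham over time.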

Other observations

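Among the 21 measured cholesterol synthesis genes, 0 rose, 10 fell and 11 did not pass, with 10 passing adjusted over the list alone. Idi1 and Acat2, of isoprenoid and sterol synthesis, fell by 1.20 ± 0.22 and 0.81 ± 0.10. These genes averaged -0.37 (-0.37 with slide as a block, -0.42 to -0.33 within slides, camera adjusted p = 3.08e-07, adjusted p = 0.156 with an estimated correlation). These values are of HIPC against Sham at 24 h (limma, adjusted p from 6.27e-08 to 7.26e-05).

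Of the tests that follow, the count of myelin members and both tests on time labels were chosen after the results were seen. Myelin genes in HIPC already averaged 0.56 over Sham at 0 h (0.424 to 0.705, Sham -0.121 to 0.291), -0.53 at 8 h and 0.325 at 24 h. At 3 h the mean was 1.79. With region markers as covariates the mean was 1.29, 0.723 of the value. Of 20 members 17 passed, all among the 18 that passed without. The markers held no white matter list, so region stays open as a cause. Mbp went from 2.98 ± 0.50 to 2.09 ± 0.38 and passed in both (limma, adjusted p = 0.000398 with the covariates). Sex as a covariate gave 1.74 (0.974 of the value), which argues little, since Sham held 2 females and 2 males and HIPC 1 and 2.

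Arrays of 0 and 8 h lay apart from those of 3 and 24 h, and slide 1 of 0 h lay between. Across genes, which are not independent replicates, the difference of slide 1 from the other 0 h slides correlated at 0.884 with that of 3 and 24 h arrays from 8 h arrays. The correlation restates the place of slide 1 on the first principal component, seen before, and adds no support. A batch of array processing shared by slide 1 with those slides stays open as a candidate explanation. Time since the procedure as the sole cause is argued against by slide 1 itself, which lay from -0.8 to 4.6 where the other 0 h slides lay from 42.4 to 50.4.

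Splits of the same arrays into groups of the same sizes, 35 for each comparison, were counted when they gave as many genes, the real one included. HI against Sham gave 6 at 0 h (real 13, highest other 1290), 2 at 3 h (real 714, highest other 1360), 2 at 8 h (real 4, highest other 5), 1 at 24 h (real 2286, highest other 1618). PC against Sham gave 5 at 0 h (real 4, highest other 1506), 35 at 3 h (real 0, highest other 1), 35 at 8 h (real 0, highest other 3), 2 at 24 h (real 211, highest other 268). HIPC against Sham gave 6 at 0 h (real 36, highest other 801), 2 at 3 h (real 1389, highest other 1753), 1 at 8 h (real 6, highest other 2), 1 at 24 h (real 2552, highest other 818). HIPC against HI gave 35 at 0 h (real 0, highest other 1013), 14 at 3 h (real 1, highest other 848), 15 at 8 h (real 1, highest other 54), 1 at 24 h (real 2756, highest other 2737). Of 100 regroupings, 1 gave as many genes for the HI effect by time (real 1567, highest other 922), 5 for the interaction (109, 647) and 1 for Sham over time (9414, 6001). Where 1 is given no other split reached the real count. That is the smallest share possible over many tests, so chance is not excluded. The highest splits at 0 h put both slide 1 arrays on 1 side, where the slide block gave 16, 10, 69 and 0 genes for HI, PC and HIPC against Sham and HIPC against HI. That of HI against Sham at 3 h followed the thalamic, hypothalamic and midbrain markers, and splits with several times the real count point to a structure of the samples. Where numbers paired the arrays, 8 splits parted as many pairs, and as many genes came from 1 for HI and PC against Sham at 0 h (highest other 6 and 0), 8 for HIPC against HI at 0 h (1) and 1 for HIPC against Sham at 8 h (2), too few splits for a share under 0.05.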
